A study of Mus musculus and Rattus norvegicus with 11 samples.

How the data were processed

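Droplet 3' single-cell RNA sequencing (10x, version 2 chemistry) was made of sciatic nerve and brachial plexus cells of C57BL/6, NOD control and NOD mice labelled Icam1 knockout, with 3 libraries each, and of sciatic nerve cells of naive Lewis rats, with 2 libraries. Per the labels, mouse cells were freed with enzymes, depleted of myelin and sorted as live cells, and rat cells were purified on a density gradient without sorting. The labels name 2 sequencers with different read lengths and do not say which library ran on which.

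The authors deposited UMI counts per gene and cell barcode, as 1 matrix of 31053 genes by 16050 barcodes for mouse and 1 of 32883 genes by 12500 barcodes for rat. The other deposited files hold annotation: barcodes whose number names the library, gene symbols, a cell type name per barcode and a group code per mouse barcode. The submitters' processing notes name Cell Ranger 3.0.2 and the genome builds mm10 and Rnor_6.0. The gene annotation release, how cells were clustered and named, doublet removal and any correction for free RNA are not given in the sources used here. Barcodes with a cell type name numbered 15672 of 16050 in mouse and 12360 of 12500 in rat, and only these entered the comparisons. The group code of 0 cells differed from the group of their library. Symbols on more than 1 gene (35 in mouse, 421 in rat) were kept apart by Ensembl identifier, and 0 columns of values per sample were left unused.

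UMI counts were summed per sample and cell set with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Control libraries 2-1 and 2-2 were summed as 1 sample. A set was tested when every sample had at least 20 of its cells. The knockout contrast used nmSC, mySC, EC, myeloid cells (MC, pDC) and lymphoid cells (BC, CD4, CD8), with 2 against 3 samples. The strain contrast used nmSC, fibro, EC (EC1 in C57BL/6), myeloid cells (MP and MC against MC and pDC) and lymphoid cells (BC and TC against BC, CD4 and CD8). The plan made before the counts were seen had merged nmSC with mySC, and EC1 with EC2 and lymph cells. Those classes were split after the leading genes showed fibroblast genes in nmSC and perineurial genes in EC2, and the merged classes were kept as alternatives. Mural cells and, for the knockout contrast, fibro cells had too few cells for a gene test.

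Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with a minimum count of 10, quasi-likelihood fits without covariates and Benjamini-Hochberg adjustment over the genes tested in a set, with a threshold of 0.05. Gene lists fixed before the counts were seen were tested with camera (limma 3.58.1) on log2 CPM at its preset correlation of 0.01 and with an estimated correlation, for lists of at least 5 tested members. Cell counts per type were tested with edgeR quasi-likelihood with all cells of a sample as library size, for types with at least 20 cells. The leukocyte share was tested with an exact two-sided permutation test. Cell types of C57BL/6 and rat were described by shares and by the 10 genes with the largest CPM ratio to the other types.

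Genes were named by a rule written before the counts were seen: Icam1, the 6 rising and 6 falling genes of a set with the largest change among those past the threshold with a mean log2 CPM of at least 5 and separated groups, and up to 4 members of each list. Examples in the text are a part of these, and some genes that the rule names are not reported here. Unnamed gene models, clone names and sex-linked genes were left out of the first part, Xist standing for the sex-linked list. Gm10260 and Rnaset2a, and Rpl27, Sap18, Tpm3, C1ra and C1s1 with their copies, were named after their values were seen. A gene without UMIs in 1 group is given with the smallest fold that 3 counts there would allow, and one with 1 to 3 UMIs with the ratio of pooled rates and its 95% exact interval. Shares of single samples carry Clopper-Pearson intervals, which cover counting error only.

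Alternatives fixed before the counts were seen were control libraries 2-1 and 2-2 as separate samples, RLE size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, thinning to equal cells, removal of Scrublet doublets (scanpy 1.11.5), leaving out each sample and replicate number as a block. Scrublet called between 0.143% and 2.38% of barcodes per library. Chosen after seeing the data were the knockout libraries summed as 1 sample, the use of the merged classes of the first plan as alternatives to the split ones, CD4 cells alone, lymphoid cells without barcodes over 20% haemoglobin and a batch term for library 1 of both strains, which had the lowest mitochondrial shares (1.04% and 0.655%). The 3 libraries labelled Icam1 knockout had cell type shares that did not differ beyond sampling (permutation p = 0.117, 0.94 and 0.065), while C57BL/6 libraries differed (permutation p = 0.001 for each pair).

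Free RNA was estimated per library from the T cell marker list: the CPM of that list in a nerve cell set, divided by its CPM in the whole library, times the library CPM of a gene gave the predicted rise. This estimate also takes in doublets of nerve cells with T cells. Near-identical copies were genes whose last 500 transcript bases (GENCODE M21) matched another gene at 95% identity or more over at least 90 bases in BLAST+ 2.17.0, and their share among called genes was set against 1000 draws of uncalled genes of like expression. The difference between the knockout changes of mySC and nmSC was tested with an interaction term in edgeR. Figures were drawn with matplotlib 3.10.9.

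The tests were run on simulated data with known answers. Between 64% and 91% of 4-fold changes were found in 9 of the 10 gene sets and 21% in lymphoid cells of the strain contrast, 2-fold changes were found at 1% to 67%, and at most 6.73% of called genes were false. Of 19 unchanged lists per set 0 were called. An 8-fold change of a cell type share was found in 59% of 100 simulations. These used a chosen dispersion of 0.3, alike in both groups, whereas NOD control samples spread far more than the libraries labelled Icam1 knockout. The 59% therefore need not hold for the share tests of these data. The interaction test found 62% of 4-fold differences with 9.49% false calls, above the threshold aimed at. A difference that missed the threshold is therefore not shown to be absent at this depth.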

Results

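Single cells of peripheral nerve were profiled by droplet 3' RNA sequencing in 9 mouse and 2 rat libraries. The mouse cells came from sciatic nerve and brachial plexus: 3 libraries from C57BL/6 mice, 3 from NOD control mice and 3 labelled Icam1 knockout on the NOD background. NOD is an inbred strain prone to autoimmunity, and Icam1 encodes an adhesion molecule that leukocytes bind through integrins. The series describes its NOD mice as a model of chronic autoimmune neuritis and its C57BL/6 mice and Lewis rats as healthy nerve. Control libraries 2-1 and 2-2 share a number in their titles, so they were summed as NOD control 2, and the comparisons rest on 3 C57BL/6, 2 NOD control and 3 Icam1 knockout samples.

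The C57BL/6 libraries 1, 3 and 4 held 1200, 3800 and 400 cell barcodes with 993033, 6631004 and 571042 UMIs. NOD control libraries 1, 2-1 and 2-2 held 1400, 2000 and 2000 barcodes with 1217214, 1427520 and 1965029 UMIs. The libraries labelled Icam1 knockout, numbers 1 to 3, held 1575, 1825 and 1850 barcodes with 2235353, 2124358 and 1977541 UMIs. The rat libraries held 6500 and 6000 barcodes with 19074026 and 17958844 UMIs. Median depth per barcode ran from 591 UMIs in NOD control 2-1 to 1530 in C57BL/6 library 3 and was 2647 and 2670 in the rat libraries. Cell types carry the deposited names, given here without expansion where the leading genes do not bear them out. Every p-value below measures only the spread between these libraries. That spread may be technical, since the labels do not say that each library came from separate animals. Cell type shares of the 3 libraries labelled Icam1 knockout did not differ beyond sampling (permutation p = 0.117, 0.94 and 0.065). Those of control libraries 2-1 and 2-2, summed as 1 sample, did (permutation p = 0.049). Summed UMI counts differed beyond permuted cells in CD8 for each pair of libraries labelled Icam1 knockout (permutation p = 0.03, 0.03 and 0.01). They also did in BC for libraries 1 and 2 and 1 and 3 (0.03 and 0.01) and in CD4 for 2 and 3 (0.01). No tested pair differed in nmSC, mySC or MC (lowest 0.09), whereas control libraries 2-1 and 2-2 did in nmSC and mySC (0.01 each). The libraries labelled Icam1 knockout may still be runs of 1 sample, and p-values of that contrast may be too small.

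Icam1 transcripts (chr9:21015985-21028817, plus strand, mm10) were counted in every mouse library and were most abundant in those labelled Icam1 knockout. Counts normalised to library total (CPM) were 246 (550 UMIs, 95% exact Poisson interval 225.9 to 267.5), 259.4 (551 UMIs, 238.2 to 282) and 254.4 (503 UMIs, 232.6 to 277.6) in the libraries labelled Icam1 knockout. NOD control libraries 1, 2-1 and 2-2 had 94.48 (78 to 113.4), 44.13 (33.91 to 56.46) and 54.96 (45.09 to 66.36) CPM. The C57BL/6 libraries 1, 3 and 4 had 81.57 (64.78 to 101.4), 88.52 (81.51 to 95.98) and 47.28 (31.16 to 68.79) CPM. The labels do not give which part of the gene was deleted, nor does a 3' tag report on the rest of the transcript, so these counts check neither the genotype nor the protein. Intervals of this kind cover counting error only.

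Which cells made up the nerve in NOD mice with and without the knockout label was compared as shares of annotated cells. Leukocytes took 91.7% ± 0.185 (SD, n = 3) of cells in the libraries labelled Icam1 knockout and 21.4% ± 17.7 (SD, n = 2) in NOD control, a difference of 70.3 percentage points. An exact two-sided permutation test gave p = 0.1, the smallest that the 10 possible splits allow. NOD control 1 had 8.857% leukocytes (95% Clopper-Pearson interval 7.421 to 10.47) and NOD control 2 had 33.9% (32.42 to 35.4). Leukocytes outnumbered endothelial cells 57.4-fold ± 4.66 (SD, n = 3) in the libraries labelled Icam1 knockout and 4.58-fold ± 1.47 (SD, n = 2) in NOD control. In the C57BL/6 libraries 25.29%, 7.501% and 49.62% of cells were leukocytes.

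Cells named CD8 rose from 0.677% ± 0.655 (SD, n = 2) of NOD control cells to 25.3% ± 0.26 (SD, n = 3) with the knockout label. Their log2 fold change was 5.14 ± 0.90 (SE, adjusted p = 0.0029, edgeR quasi-likelihood test on cell counts with Benjamini-Hochberg adjustment over 11 types). It was 4.46 without NOD control 1 and 6.83 without NOD control 2. With the knockout label their leading genes mixed Cd8a, the T cell co-receptor, with the natural killer receptor genes Klrc1, Klra7 and Klre1. The 48 such cells of NOD control led with Gzma, Xcl1, Klra1 and Ncr1, and Cd8a was not among their leading genes. Cells named CD4 led with Cd40lg and Tnfsf8 with the label and with Tcrg-C4 and Areg in NOD control. The same name may therefore cover unlike cells in the groups. Cells named CD4 rose from 6.75% ± 5.61 to 39.8% ± 1.05 (log2 2.55 ± 0.75, edgeR adjusted p = 0.027), and pDC from 0.206% ± 0.112 to 0.899% ± 0.228 (log2 2.19 ± 0.71, adjusted p = 0.032). Fibro cells, which lead with epineurial genes such as Sfrp2 and Pi16, fell from 11.9% ± 6.51 to 0.384% ± 0.108 (log2 −4.92 ± 0.68, edgeR adjusted p = 0.0020). Cells named nmSC fell from 50.5% ± 27.7 to 3.63% ± 0.94 (log2 −3.80 ± 0.63, edgeR adjusted p = 0.0029). Since all shares are parts of the same total, falls of nerve cell types and rises of leukocyte types are not separate findings. The perineurial EP cells fell from 54 cells, 21 and 32 of them in NOD control libraries 2-1 and 2-2, to 1 (log2 −4.90 ± 1.46) and vSMC/PC from 76 cells to 14 (log2 −2.06 ± 0.70), with edgeR adjusted p = 0.027 and 0.035. B cells (log2 1.21 ± 1.20), MC (log2 −0.10 ± 0.52), EC (log2 −1.42 ± 0.59) and mySC (log2 −2.05 ± 0.98) did not pass the test. Without NOD control 2 the log2 fold change was 5.41 for B cells and 0.756 for mySC, a change of sign for mySC. Without NOD control 1 the values were 0.251 and −2.95. Of the 7 types that passed, CD4, pDC and vSMC/PC no longer did when any one of the libraries labelled Icam1 knockout was left out (lowest adjusted p = 0.0868, 0.127 and 0.143). pDC and vSMC/PC also missed the threshold without NOD control 2 (0.0603 and 0.226), and EP, with too few cells left, was not tested, while 10 types passed without NOD control 1. With replicate number as a block 2 types passed, CD8 and fibro (adjusted p = 0.0368 each), and with the 3 libraries labelled Icam1 knockout summed as 1 sample 0 types passed in edgeR and 1 had an unadjusted p under 0.05 (CD8 adjusted p = 0.299, fibro 0.351).

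**Figure D1:**
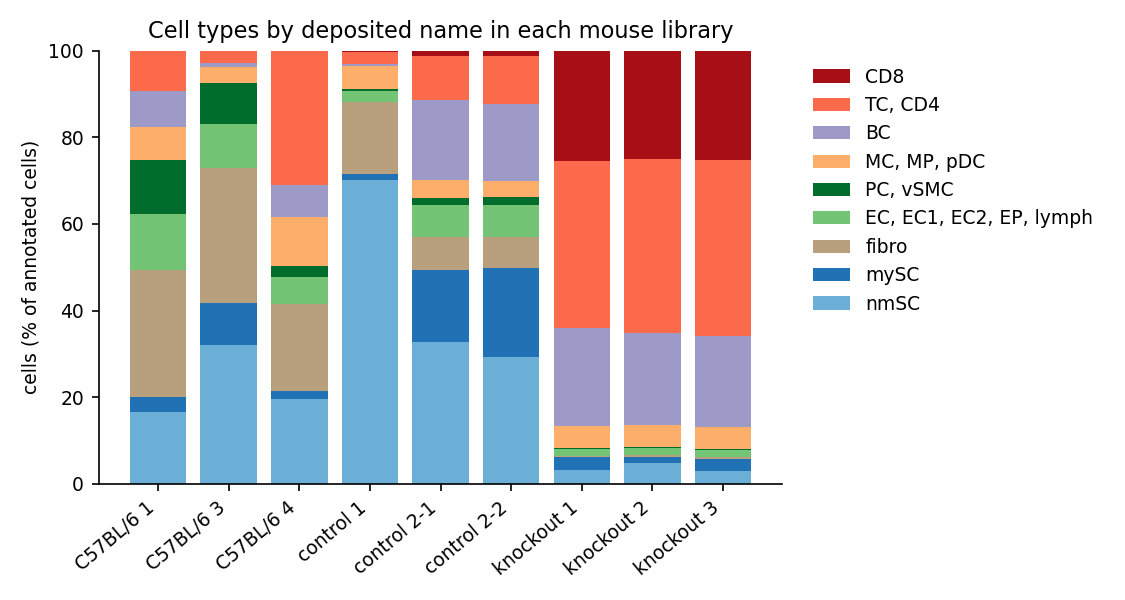
Percent of annotated cells by deposited cell type (similar names joined) in each of the 9 mouse libraries, as stacked bars. Cells named CD8 take 25% to 25.5% of each library labelled Icam1 knockout and at most 1.14% of a NOD control sample.

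Gene expression was compared cell type by cell type between the libraries labelled Icam1 knockout and NOD control (n = 3 and 2), to ask which genes differ within each nerve cell type. Values are log2 fold changes ± SE of edgeR quasi-likelihood fits on summed UMI counts, with Benjamini-Hochberg adjusted p. Mean CPM of single genes beside a fitted change use TMM-scaled library sizes and weigh samples equally, so their ratio can differ from the fitted change.

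In mySC, the cells carrying the myelin genes, interferon-induced and antigen presentation genes rose while myelin and cholesterol synthesis genes fell. In all 195 of 1711 tested genes changed, 96 up and 99 down. All 10 tested members of the interferon-gamma list rose (10 adjusted over the list alone), among them the induced GTPase gene Ifi47 (5.67 ± 0.52, adjusted p = 2.7e-07). The related GTPase gene Iigp1 (chr18:60376027-60392634) had 76 UMIs against 1 in NOD control, a 219-fold higher rate (95% interval 38.1 to 8762; edgeR adjusted p = 2.7e-07). All 11 MHC class I members rose (11 adjusted over the list alone): H2-D1 and H2-K1, the classical heavy chains (4.31 ± 0.40 and 3.51 ± 0.32), and the immunoproteasome gene Psmb8 (3.38 ± 0.34). H2-D1 (chr17:35262730-35267499) went from a mean of 392 to 11625 TMM-scaled CPM (adjusted p = 2.9e-07). Of 7 type I interferon genes 6 rose (7 adjusted over the list alone), with Bst2, a tether of budding virus, at 2.28 ± 0.36, and of 5 MHC class II genes 3 rose (3 adjusted over the list alone), with H2-Eb1 at 1.85 ± 0.39. These 4 lists passed camera at the preset correlation (adjusted p = 4.6e-11, 1.1e-12, 1.3e-05 and 0.0096). With an estimated correlation none did: adjusted p = 0.056 for interferon-gamma, 0.0808 for MHC class I, 0.185 for type I interferon and 0.364 for MHC class II with an estimated correlation.

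Of 15 myelin genes in mySC 11 fell (11 adjusted over the list alone). Markers of the cell type itself were also lower: the pan Schwann list went from 2457 ± 311 CPM (SD, n = 2) in NOD control to 760 ± 57.8 (SD, n = 3) with the knockout label and the myelinating Schwann list from 3317 ± 810 to 642 ± 179, while the nonmyelinating list stood at 198 ± 31.6 and 201 ± 49.5. Ugt8a, which makes the myelin lipid galactosylceramide, fell by 3.45 ± 0.39 and Pmp22 by 2.77 ± 0.36. All 5 tested cholesterol synthesis genes fell (5 adjusted over the list alone), including Msmo1 (−2.38 ± 0.35) and Fdps (−2.29 ± 0.39). Camera called the myelin list (adjusted p = 9.0e-09; adjusted p = 0.103 with an estimated correlation) and the cholesterol list (adjusted p = 8.4e-06; adjusted p = 0.0808 with an estimated correlation). Of 9 collagen and matrix genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with the matrix gene Postn at 2.27 ± 0.40 and camera adjusted p = 0.291. The secreted phosphoprotein gene Spp1 fell by 4.81 ± 0.44, and Mfap5, a microfibril gene, had 1 UMI against 534, a rate 0.0054 times that of NOD control (95% interval 0.000136 to 0.0302).

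Markers of other states moved with these genes. Of 9 mitochondrial oxidative phosphorylation genes in mySC 3 rose (7 adjusted over the list alone), mt-Co2 by 2.23 ± 0.31, with camera adjusted p = 1.4e-05 and adjusted p = 0.25 with an estimated correlation. Immediate early genes, which cell dissociation induces, fell for 3 of 14 members (7 adjusted over the list alone), Klf2 by 1.47 ± 0.29 (camera adjusted p = 0.0021; adjusted p = 0.271 with an estimated correlation). Xist, the X-inactivation transcript, fell by 1.43 ± 0.26 in mySC and by 1.29 ± 0.18 in nmSC (edgeR adjusted p = 0.00056 and 0.0032). Xist stands for the sex-linked genes, and whether the groups held the same sexes was not tested. The T cell marker list stood at 47.8 ± 11.7 CPM (SD, n = 3) in mySC with the knockout label and at 4.65 ± 6.58 in NOD control (n = 2). Ccl5, a T cell chemokine, rose by 5.05 ± 0.51 in mySC, where free leukocyte RNA predicted between 74.2% and 207% of its rise per library. NOD control 1 held only 20 mySC with 13094 UMIs; 403 genes passed without it (145 up and 258 down). Without NOD control 2 the count was 50 (36 up and 14 down) and without library 3 labelled Icam1 knockout it was 79. Iigp1, Msmo1, Fdps and Klf2 then missed the threshold without NOD control 2 (adjusted p = 0.0514, 0.249, 0.208 and 0.437), as did Fdps without library 3 labelled Icam1 knockout (0.0515).

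**Figure D2:**
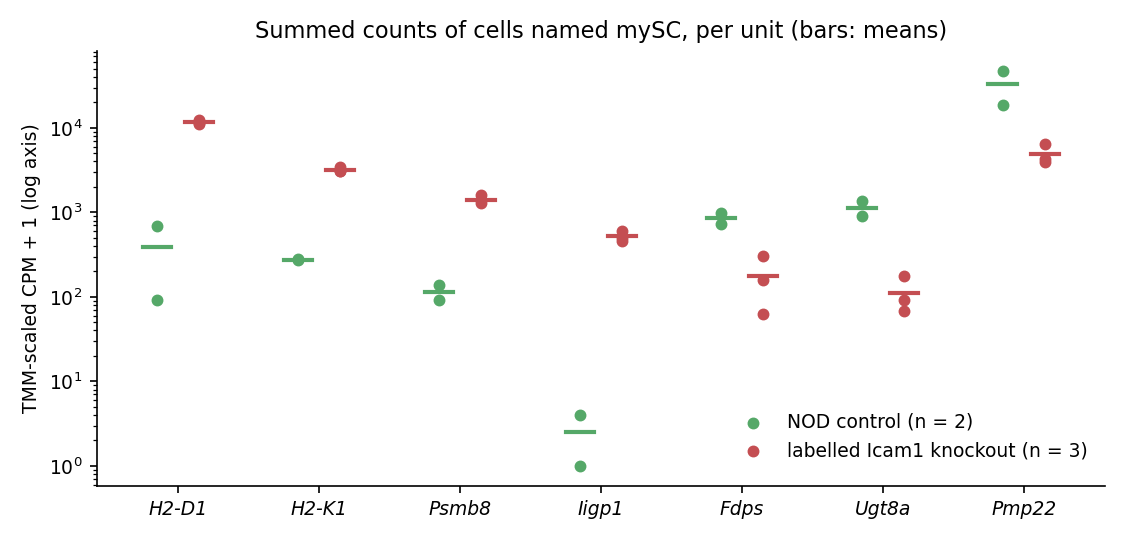
TMM-scaled CPM + 1 on a log axis of 7 genes in mySC, 1 point per sample with bars for group means, in NOD control (n = 2) and the libraries labelled Icam1 knockout (n = 3). H2-D1 has a mean of 392 TMM-scaled CPM in NOD control and 11625 with the knockout label.

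Cells named nmSC lead with endoneurial fibroblast genes and carried few Schwann cell transcripts. The pan Schwann markers averaged 43.6 ± 27 CPM (SD, n = 2) in nmSC of NOD control and 2457 ± 311 CPM in mySC. In these cells 82 of 2101 genes changed with the knockout label, 50 up and 32 down. Collagen and matrix genes fell for 6 of 14 members (11 adjusted over the list alone): Sparc, a collagen-binding matrix protein (−1.63 ± 0.27, edgeR adjusted p = 0.0065), Col1a1 (−1.19 ± 0.21) and Col6a1 (−1.23 ± 0.19). Of 8 cholesterol synthesis genes 2 fell (5 adjusted over the list alone), Fdps by 2.22 ± 0.30 (edgeR adjusted p = 0.0029) and Fdft1 by 1.93 ± 0.46. Camera called both lists (adjusted p = 1.9e-09 and 2.5e-05; adjusted p = 0.0883 and 0.167 with an estimated correlation). Immediate early genes rose for 2 of 15 members (8 adjusted over the list alone), Junb by 1.22 ± 0.21 (camera adjusted p = 3.1e-05; adjusted p = 0.167 with an estimated correlation). Of 7 MHC class I genes 1 rose, H2-D1 by 1.07 ± 0.27 (4 adjusted over the list alone; camera adjusted p = 0.015; adjusted p = 0.232 with an estimated correlation). Wif1, a secreted Wnt inhibitor, rose by 2.57 ± 0.58. Mitochondrial genes rose for 3 of 10 members (4 adjusted over the list alone), mt-Co2 by 1.97 ± 0.22 (camera adjusted p = 3.1e-05; adjusted p = 0.232 with an estimated correlation). Icam1 rose by 1.97 ± 0.44 in nmSC (edgeR adjusted p = 0.03), and leaving out library 1, 2 or 3 labelled Icam1 knockout ended that call (adjusted p = 0.163, 0.199 and 0.0896). Its log2 fold change stayed at 2.03, 1.86 and 1.90 in those fits, which tested 5965, 5723 and 5760 genes instead of 2101.

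The leukocyte genes Ccl5 (5.43 ± 0.45), Nkg7 (4.84 ± 0.61), Rgs1 (3.82 ± 0.87) and Ms4a4b (3.75 ± 0.79) also rose in nmSC. The T cell marker list there stood at 41.1 ± 9.76 CPM (SD, n = 3) with the knockout label and 4.38 ± 5.31 in NOD control (n = 2). The nmSC count moved with single samples: 9, 9 and 17 genes passed without library 1, 2 or 3 labelled Icam1 knockout, 243 without NOD control 1 (106 up and 137 down) and 348 without NOD control 2 (153 up and 195 down), which turned the balance of directions. With the libraries labelled Icam1 knockout summed as 1 sample 3 genes passed, and with DESeq2 53. Fits without library 1, 2 or 3 labelled Icam1 knockout tested 5965, 5723 and 5760 genes instead of 2101, so their adjustment ran over more genes. Without library 1 the adjusted p of Sparc was 0.0707, of Col1a1 0.0806, of Col6a1 0.124, of Fdft1 0.315, of Junb 0.163, of H2-D1 0.422 and of Wif1 0.119. These 7 genes missed the threshold without library 2 or 3 as well (adjusted p between 0.0611 and 0.18), whereas Ccl5, Nkg7, Fdps and mt-Co2 passed without any one sample. Rgs1 missed it without NOD control 1 (0.202) and, with Ms4a4b, without library 2 (0.118 and 0.107), Ms4a4b without library 1 (0.0737), and Xist without library 1 or 2 (0.0815 and 0.0726).

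EC of the libraries labelled Icam1 knockout lacked Ccl21a (chr4:42772860-42773993), a chemokine of lymphatic endothelium. It had 342 UMIs in NOD control and none with the knockout label, at least 52.6-fold lower (edgeR adjusted p = 0.0042). The lymphatic endothelial list in EC stood at 7.01 and 274 CPM in the 2 NOD control samples and had no UMI among 90230 with the knockout label. In all 14 of 538 tested genes changed, 6 up and 8 down. The fibroblast genes Dcn (−3.99 ± 0.61), Apod (−3.65 ± 0.41), Lum (−3.64 ± 0.52) and Gsn (−3.45 ± 0.45) fell, and the pan fibroblast list stood at 846 ± 397 CPM (SD, n = 2) in EC of NOD control and 58.6 ± 24.4 (SD, n = 3) with the knockout label. Ccl5 rose by 4.92 ± 0.46, where free RNA predicted between 70.3% and 86.1% of the rise per library, and mt-Co2 by 2.56 ± 0.33. Of 7 MHC class I genes none passed over all genes and 6 rose adjusted over the list alone, with H2-D1 at 0.89 ± 0.23 (camera adjusted p = 0.00075; adjusted p = 0.316 with an estimated correlation). Of 7 mitochondrial genes 2 rose (6 adjusted over the list alone; camera adjusted p = 2.3e-05; adjusted p = 0.316 with an estimated correlation). Leaving out library 1 labelled Icam1 knockout gave 7 genes and ended the calls of Ccl21a (adjusted p = 0.164) and Dcn (0.141). Without NOD control 1 or 2, 37 and 29 genes passed, and H2-D1 was called without NOD control 1 (adjusted p = 0.0168).

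In the myeloid cells (MC and pDC) interferon-induced and MHC class I genes rose. In all 576 of 3514 genes changed, 285 up and 291 down. The chemokine genes Cxcl13 and Cxcl9 rose at least 45.2-fold and 18.7-fold from no UMI in NOD control. Interferon-gamma genes rose for 10 of 13 members (12 adjusted over the list alone), with Gbp2 at 4.10 ± 0.36, and type I interferon genes for 10 of 11 (10 adjusted over the list alone), with the regulator gene Irf7 at 3.37 ± 0.40. MHC class I genes rose for 10 of 11 members (11 adjusted over the list alone), with the peptide transporter gene Tap2 at 2.25 ± 0.34. Camera called these 3 lists (adjusted p = 8.3e-10, 1.6e-06 and 1.4e-06), and with an estimated correlation it did not (adjusted p = 0.124, 0.102 and 0.102 with an estimated correlation). Retnla, a secreted marker of alternatively activated macrophages, fell by 5.74 ± 0.62 (edgeR adjusted p = 1.6e-05), and Pf4 by 5.60 ± 0.33 (adjusted p = 6.4e-08). The folate receptor gene Folr2 fell by 5.22 ± 0.53. Lyve1, another receptor gene of vessel-associated macrophages, had 2 UMIs against 44, a rate 0.0201 times that of NOD control (95% interval 0.00236 to 0.077). The macrophage marker list stood at 1873 ± 236 CPM (SD, n = 3) in MC with the knockout label and at 2695 ± 301 in NOD control (n = 2), the monocyte list at 802 ± 107 and 307 ± 98.4 and the T cell list at 34.2 ± 10.7 and 6.28 ± 4.78. Immediate early genes fell for 10 of 16 members (12 adjusted over the list alone), Egr1 by 2.94 ± 0.38 (camera adjusted p = 1.2e-05; adjusted p = 0.31 with an estimated correlation). pDC made up 46 of 257 such cells with the knockout label and 9 of 229 in NOD control. Sh3bgr, a leading gene of pDC, rose at least 10.9-fold, and Nkg7, a leukocyte granule gene, at least 12.1-fold. Median depth was 2207 to 3023 UMIs per cell against 903 and 1143. Without NOD control 2 the count was 349, and Cxcl13 (adjusted p = 0.0639) and Sh3bgr (0.0969) missed the threshold.

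In the sum of lymphoid cells (BC, CD4 and CD8) T cell effector genes rose with the knockout label. In all 1743 of 8999 genes changed, 946 up and 797 down. Klrk1, the activating receptor NKG2D, had 923 UMIs against 3 (60.5-fold by rate, 95% interval 20.6 to 294; edgeR adjusted p = 4.4e-24), and the granzyme gene Gzmk 893 against 3 (58.5-fold, 20 to 284). Of 14 T cell effector genes 12 rose (12 adjusted over the list alone), among them the checkpoint receptor genes Pdcd1 (4.58 ± 0.38) and Ctla4 (4.39 ± 0.37) and the cytokine gene Ifng (4.50 ± 0.40). Camera gave adjusted p = 1.8e-05 and adjusted p = 0.0838 with an estimated correlation. Ccl5 (chr11:83525778-83530518) rose by 3.70 ± 0.34, from 1212 to 14941 TMM-scaled CPM. Interferon-gamma genes rose for 11 of 16 members (11 adjusted over the list alone), with Gbp2 at 2.01 ± 0.32, and MHC class I genes for 8 of 12 (10 adjusted over the list alone), with Tap1 at 1.15 ± 0.24 (camera adjusted p = 0.0046 and 0.0054; adjusted p = 0.673 for both with an estimated correlation). Icam1 rose by 1.65 ± 0.25 (edgeR adjusted p = 1.2e-08) in lymphoid cells and stood at 0.42 ± 0.26 in myeloid cells (adjusted p = 0.31).

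Collagen and matrix genes fell in the same lymphoid cells. All 10 tested collagen genes fell (10 adjusted over the list alone), Col1a1 by 4.55 ± 0.27, and this list passed camera with the preset correlation (adjusted p = 3.2e-16) and adjusted p = 0.0481 with an estimated correlation. The pan fibroblast marker list was lower as well, at 80.5 ± 15.3 CPM (SD, n = 3) in CD4 with the knockout label and 430 ± 72.4 in NOD control (n = 2), and in BC at 64.9 ± 8.91 with the label and 462 in NOD control 2, so RNA of nerve cells in the lymphoid barcodes was not separated from expression. Retnla, a macrophage gene, fell by 4.93 ± 0.29. Myelin genes fell for 6 of 7 members (6 adjusted over the list alone; camera adjusted p = 0.0572), and MHC class II genes for 6 of 11 (6 adjusted over the list alone; camera adjusted p = 0.64), the class II transactivator gene Ciita by 2.26 ± 0.25. Cholesterol synthesis genes fell for 7 of 16 members (7 adjusted over the list alone), Fdps by 1.72 ± 0.28 (camera adjusted p = 2.0e-05; adjusted p = 0.0838 with an estimated correlation). Mitochondrial genes rose for 6 of 13 members (6 adjusted over the list alone), mt-Atp6 by 2.00 ± 0.32 (camera adjusted p = 0.018; adjusted p = 0.673 with an estimated correlation). The haemoglobin gene Hbb-bs rose by 5.18 ± 0.52, where 6 lymphoid barcodes had over 20% haemoglobin UMIs. Without those barcodes 1796 genes passed. Each of the 15 genes named for lymphoid cells in this contrast, Hbb-bs included, then kept direction and side of the threshold. B cells, which carry MHC class II genes, made up 1107 of the 4442 lymphoid cells with the knockout label and 723 of 1233 in NOD control, and make-up was not separated from expression. CD8 cells made up 1294 of the 4442 lymphoid cells with the knockout label and 48 of 1233 in NOD control. In CD4 cells alone, an alternative chosen after seeing the data, 744 genes changed, 458 up and 286 down. Leading genes of CD4 differed between the groups, so make-up was not separated from expression in that fit either. Without NOD control 2, which left 49 control cells, 262 genes passed and Ifng, Gbp2, Fdps, Icam1 and Hbb-bs did not (adjusted p = 0.558, 0.136, 0.216, 0.0766 and 0.144), while the value of Ciita turned to 8.06 ± 5.09. Without NOD control 1, 2524 passed. With replicate number as a block 112 genes rose and 162 fell, and with the libraries labelled Icam1 knockout summed as 1 sample 47 rose and 120 fell.

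The strain comparison asked how nerve cells of NOD control mice differ from those of C57BL/6 mice (n = 2 and 3). It shares both NOD control samples with the knockout contrast, so a shift in those samples enters the contrasts with opposite signs. Changes of mt-Co2 in nmSC, Ccl21a in EC and Klrk1 in lymphoid cells had opposite signs and were not told apart from such a shift. No cell type share passed: edgeR quasi-likelihood called 0 of 9 types, and 1, the mural cells, had an unadjusted p under 0.05 in this model across types (8.14% ± 5.05 in C57BL/6 and 1.12% ± 0.883 in NOD control, log2 −2.84 ± 1.22, adjusted p = 0.316). Cells named nmSC took 22.7% ± 8.18 (SD, n = 3) in C57BL/6 and 50.5% ± 27.7 (SD, n = 2) in NOD control, fibro cells 26.8% ± 5.98 and 11.9% ± 6.51, and T cells 14.3% ± 14.7 and 7.43% ± 6.26.

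In nmSC of NOD control the lipid carrier gene Apoe was higher by 3.82 ± 0.47 (795 to 11290 TMM-scaled CPM, edgeR adjusted p = 4.5e-05) and Cebpb, a transcription factor gene of inflammatory responses, by 3.63 ± 0.44 (adjusted p = 3.8e-05). Of 7691 tested genes 175 changed, 106 up and 69 down. The immediate early list rose for 2 of 16 members (2 adjusted over the list alone), Jund by 2.01 ± 0.35 and Klf2 by 1.83 ± 0.42 (camera adjusted p = 0.005; adjusted p = 0.971 with an estimated correlation). Mitochondrial genes fell for 6 of 12 members (7 adjusted over the list alone), mt-Nd4l by 2.84 ± 0.34 and mt-Co2 by 2.52 ± 0.46 (camera adjusted p = 3.3e-09; adjusted p = 0.971 with an estimated correlation). The complement gene C4b rose by 2.02 ± 0.45. Among the genes with the largest falls were the ribosomal protein gene Rps18 (chr17:33951999-33956001, −5.39 ± 0.49, adjusted p = 1.5e-06) and Pttg1, which codes for securin (−5.54 ± 0.46, adjusted p = 4.0e-07). Of the 175 genes 63 have a near-identical copy elsewhere in the annotation. Without C57BL/6 library 3 the count was 48 (17 up and 31 down), and thinning to equal cells gave 33 (15 up and 18 down). Without that library C4b was not called (adjusted p = 0.369), nor was it without NOD control 2 (0.172); Klf2 was not called without C57BL/6 library 1 or 4 (0.078 and 0.128).

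Rps18 and its near-identical copy Gm10260 (chr13:97760072-97760632) differed in opposite directions between the strains in nmSC. Rps18 had 2642, 1512 and 1416 CPM in C57BL/6 libraries 1, 3 and 4 and 51.4, 48.6 and 43.5 CPM in NOD control libraries 1, 2-1 and 2-2. Gm10260 had 15.1, 1.69 and 0 CPM (0 of 88308 UMIs in library 4, which allows up to 34 CPM) against 1033, 1006 and 1094. Their sum was 2657, 1514 and 1416 CPM against 1084, 1054 and 1138. Libraries 1, 2 and 3 labelled Icam1 knockout, also on the NOD background, had 40.5, 16.6 and 0 CPM of Rps18, close to or below their counting floor. Their Gm10260 stood at 1084, 1251 and 1133 CPM. The sum of Rpl27 and its copy Rpl27-ps3 was 1079, 425 and 464 CPM against 61.4, 234 and 205, and that of Sap18 and Sap18b was at least 353 CPM in each C57BL/6 library and at most 186 in each NOD control library. For Tpm3 and Tpm3-rs7 the sums were 151 to 184 CPM against 170 to 198.

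**Figure D3:**
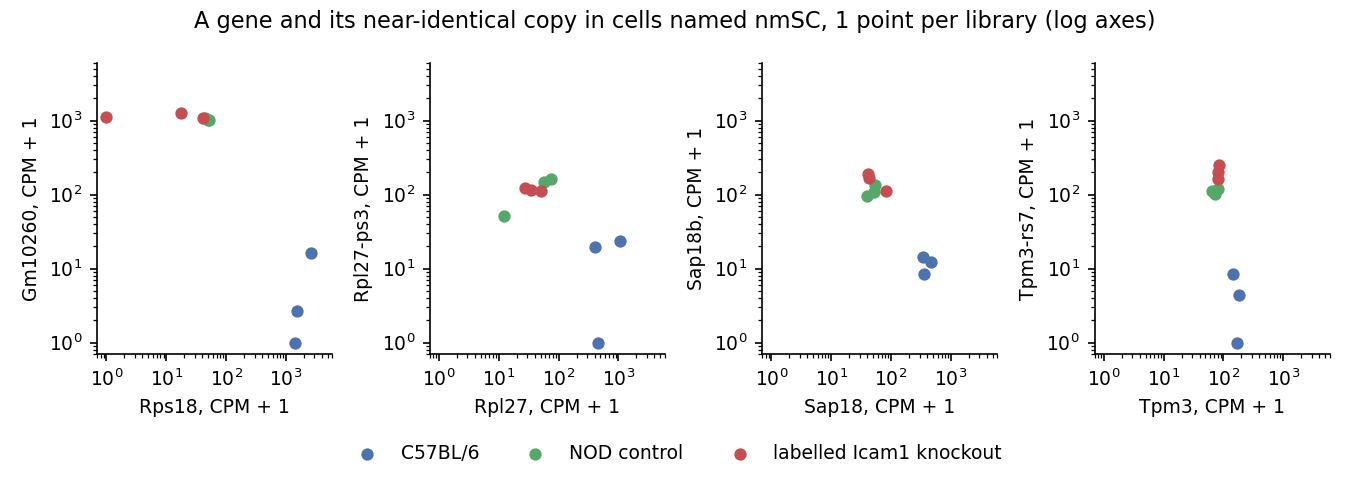
CPM + 1 of a gene (x axis) and of its near-identical copy (y axis) in nmSC, for 4 pairs on log axes, 1 point per mouse library coloured by group. C57BL/6 libraries lie to the right, with 1416 to 2642 CPM of Rps18, and NOD control libraries at the top, with 1006 to 1094 CPM of Gm10260. Libraries labelled Icam1 knockout lie at the top as well, with 1084 to 1251 CPM of Gm10260.

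Fibro cells of NOD control had higher Cxcl14, a chemokine gene (2.48 ± 0.32, edgeR adjusted p = 0.00034), and Prg4, the lubricin gene (2.95 ± 0.43, adjusted p = 0.001), and lower Mmp3, a matrix-degrading protease gene (−2.26 ± 0.40, adjusted p = 0.0056). Of 4780 genes 87 changed, 45 up and 42 down, and 41.9% of those searched had a near-identical copy. Apoe rose by 2.85 ± 0.48 there but not past the threshold without C57BL/6 library 3 or 4 (adjusted p = 0.0641 and 0.0836). Mitochondrial genes fell for 4 of 12 members (7 adjusted over the list alone), mt-Nd2 by 2.81 ± 0.41 (camera adjusted p = 5.6e-09; adjusted p = 0.335 with an estimated correlation). None of 9 type I interferon genes passed over all genes and 3 fell adjusted over the list alone (camera adjusted p = 0.00018; adjusted p = 0.335 with an estimated correlation). Without C57BL/6 library 3 the count of genes was 55 (23 up and 32 down).

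In EC, Ccl21a was 8.07 ± 1.01 higher in NOD control (edgeR adjusted p = 0.0026), where the lymphatic marker list stood at 7.01 and 274 CPM in the 2 samples; C57BL/6 lymphatic cells carry their own deposited name. Of 2091 genes 41 changed, 19 up and 22 down, and 48.8% had a near-identical copy. Collagen genes rose for 1 of 7 members (1 adjusted over the list alone; camera adjusted p = 0.0014; adjusted p = 0.427 with an estimated correlation). Mitochondrial genes fell for 2 of 10 members (4 adjusted over the list alone; camera adjusted p = 0.00028; adjusted p = 0.427 with an estimated correlation). Without NOD control 2 the count was 9.

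The strain comparison of myeloid and lymphoid cells gave 22 of 1687 and 42 of 2343 genes. Rnaset2b, a ribonuclease gene with a near-identical copy, had no UMI in myeloid cells of NOD control against 90, at least 14.3-fold lower (edgeR adjusted p = 0.028), and 2 against 91 in lymphoid cells, a rate 0.0114 times that of C57BL/6 (95% interval 0.00136 to 0.0424). Lymphoid Klrk1 had 3 UMIs against 57, a rate 0.0273 times that of C57BL/6 (95% interval 0.00546 to 0.0839), and the monocyte and T cell antigen gene Ly6c2 was lower by 5.19 ± 0.90. B cells made up 723 of 1233 lymphoid cells in NOD control and 160 of 493 in C57BL/6. The natural killer list stood at 337 ± 203 CPM (SD, n = 3) in TC of C57BL/6, at 1.65 ± 2.33 in CD4 of NOD control (n = 2) and at 383 in CD8 of NOD control 2. In C57BL/6 the myeloid cells are named MP and MC, with neutrophil genes such as Ngp and S100a8 leading the pooled MC (neutrophil list from 9.43 to 8698 CPM between libraries), whereas MC of NOD control lead with macrophage genes such as C1qa, so the myeloid sets also differ in make-up. Immediate early genes rose for 1 of 16 and 1 of 15 members (2 adjusted over the list alone in each; camera adjusted p = 0.00056 and 0.00086; adjusted p = 0.726 and 0.64 with an estimated correlation). Of mitochondrial genes 0 of 9 and 1 of 11 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.00059 and 2.8e-07; adjusted p = 0.726 and 0.64 with an estimated correlation). Without NOD control 2 the counts were 2 and 6, and Rnaset2b in myeloid and lymphoid cells (adjusted p = 0.375 and 0.487), Klrk1 (0.574) and Ly6c2 (0.508) were not called.

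The healthy C57BL/6 nerve was described without a test. Fibro cells took 26.8% ± 5.98 (SD, n = 3) of cells, nmSC 22.7% ± 8.18, T cells 14.3% ± 14.7, EC1 9.22% ± 2.92, MP 6.20% ± 2.83, B cells 5.51% ± 4.00 and mySC 5.07% ± 4.22. Cells named vSMC took 4.64% ± 2.72, PC 3.50% ± 2.39, MC 1.41% ± 1.01, lymph 0.305% ± 0.292 and EC2 0.278% ± 0.254. Leading genes of mySC included Cmtm5 and Fxyd3, and these cells had 719 ± 41.5 CPM (SD, n = 2 libraries with at least 10 such cells) of pan Schwann genes. That list stood at 760 ± 57.8 CPM (SD, n = 3) in mySC with the knockout label and at 2457 ± 311 (SD, n = 2) in NOD control. Cells named nmSC led with Angptl7, Apod and Kcnk2 and had 180 ± 10.6 CPM of endoneurial fibroblast genes but 29.7 ± 14.6 CPM of pan Schwann genes (SD, n = 3). EC2 led with the perineurial genes Lypd2, Msln and Cldn1, not with endothelial genes. EC1 led with Car4, Vwf and the lipid transporter gene of barrier vessels Mfsd2a.

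The naive Lewis rat nerve held the same cell types in both libraries at similar shares. Cells named nmSC took 31.79% (95% Clopper-Pearson interval 30.65 to 32.94) and 31.57% (30.39 to 32.77), fibro 28.38% (27.28 to 29.5) and 28.08% (26.94 to 29.25), and PF4 MC 18.29% (17.35 to 19.26) and 18.92% (17.93 to 19.94). T cells took 7.752% and 8.036%, MHC II APC 6.522% and 6.385%, vascular EC 2.584% and 2.291%, microvasculatory EC 2.46% and 2.241%, B cells 1.93% and 2.173% and mast cells 0.296% and 0.303%. Rat nmSC led with Kcnk2, Sox9 and Apod and had 91 ± 3.43 CPM (SD, n = 2) of endoneurial fibroblast genes and 12.1 ± 0.258 CPM of pan Schwann genes. The cells named vascular EC led with the lymphatic genes Mmrn1, Ccl21 and Flt4 but also with Cldn5 and Gja4. They had the highest level of 4 of 6 arterial endothelial genes, a list at 46.6 ± 9.84 CPM (SD, n = 2) there. That list stood at 7.61 ± 2.42 CPM in microvasculatory EC, which led with the venous adhesion genes Sele and Selp. PF4 MC had the highest level of 10 of 11 macrophage genes. S100a8 and S100a9 were among their leading genes in the pooled cells, with the neutrophil list at 3.36 CPM in 1 library and 299 CPM in the other. Mouse cells were sorted and myelin depleted and rat cells were not, so species and preparation were not compared.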

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

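The comparison of mySC with nmSC and all tests of explanations below, except that of near-identical copies, were chosen after the results were seen.

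The change with the knockout label differed between mySC and nmSC for 115 of 2429 genes, 50 higher and 65 lower in mySC, by the edgeR interaction term with Benjamini-Hochberg adjustment. In simulated data 9.49% of the genes this test called were false. The log2 fold change in mySC exceeded that in nmSC by 3.373 for the interferon-induced GTPase gene Gbp2, 3.39 for H2-D1 and 2.768 for H2-K1. It was lower in mySC by 1.875 (−1.875) for Klf2 and by 1.778 (−1.778) for Junb. Of the fixed lists, 9 of 11 MHC class I genes were higher and 10 of 15 immediate early genes lower in mySC. Without NOD control 2 only 13 genes were called, without NOD control 1 148, and without library 1, 2 or 3 labelled Icam1 knockout 61, 63 and 59, whereas H2-D1 passed each time with a difference between 2.99 and 6.45.

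For the higher immune-related genes in mySC and nmSC, free leukocyte RNA and a sparse control library were weighed. Free RNA does not account for the interferon and MHC class I genes of mySC: it predicted a median of at most 5.71% of the rise of 21 genes in any library. The rise of 21 of 21 genes was also seen against NOD control 2 alone. That fit leaves 1 control sample, whose spread is not measured, so it cannot decide whether the calls rest on the sparse NOD control 1. For Ccl5, Nkg7, Rgs1 and Ms4a4b in nmSC free RNA, or doublets with T cells, may be the source, as it predicted at least 74.3% of each rise (mean of 3 libraries). Genotype, sex, the make-up of mySC, and any difference in inflammation or handling of the nerves that the labels do not record, stay open for the genes of mySC as untested.

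Genes such as Rps18 were lower in NOD control while near-identical copies such as Gm10260 were higher, with a copy called the other way for 25 of 63 called genes with a copy in nmSC, 13 of 36 in fibro, 3 of 20 in EC, 5 of 16 in myeloid and 5 of 23 in lymphoid cells. Called genes had such a copy more often than the middle 95% of draws of uncalled genes in 5 of 5 cell sets (36% of 175 genes in nmSC against a median of 9.71%), and this prediction was written before its result, so counts that move between copies may be part of the source. Summed counts in nmSC cannot decide this, since reads that match both copies may be counted for neither, and each sum took in 1 copy. The sums of Rps18, Rpl27, Sap18 and Rnaset2a with a copy were lower in each NOD control library than in each C57BL/6 library. That of C1ra and C1rb was higher in each (245.3 to 494 CPM against 135.9 to 215.2). Those of C1s1 with C1s2 and of Tpm3 with Tpm3-rs7 overlapped. Read length cannot be told apart from strain, as the labels name 2 read set-ups and assign 0 libraries. In nmSC of the libraries labelled Icam1 knockout, also on the NOD background, Rps18 stood at 0 to 40.5 CPM and Gm10260 at 1084 to 1251 CPM. This pair thus differed from C57BL/6 alike in each library on the NOD background. Strain itself, through sequence variants or through expression, stays open and was not tested.

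Leukocytes took most cells of the libraries labelled Icam1 knockout. The ratio of CD8 to MC cells was at least 19.3-fold higher in each of these libraries than in either NOD control sample, so leukocyte types did not rise alike. It cannot decide whether fewer nerve cells were recovered. The ratio was chosen after the shares of both types were seen, and MC may be lost along with nerve cells. Blood carried into the cells cannot be told apart, since erythroid barcodes per 100 lymphoid cells numbered 0.653 there, 0.676 in NOD control 2, 2.67 in C57BL/6 library 4 and 0 in NOD control 1 and C57BL/6 libraries 1 and 3. Genotype, sex, and any difference in inflammation or handling of the nerves, stay open as untested explanations.

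Barcodes without a cell type name were used in no comparison, and those with over 20% haemoglobin UMIs made up 0.438% of barcodes (23 of 5250, 95% Clopper-Pearson interval 0.278 to 0.657) in the libraries labelled Icam1 knockout, 0.148% (8 of 5400) in NOD control and 0.0741% (4 of 5400) in C57BL/6.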

How the results depend on the processing

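Alternatives with knockout libraries summed, CD4 cells alone, lymphoid cells without haemoglobin-rich barcodes and a batch term were chosen after seeing the data, as was the split of the first planned classes, which serve here as merged alternatives; all others were planned, all were run, and the cause of a changed count was not tested except where fewer samples or cells remained. Of 891 values of 69 gene results named in the knockout contrast, 788 kept direction and side of the threshold, 99 lost the call, 2 gained one, 1 moved and 1 reversed. The last was Ciita of lymphoid cells, whose log2 fold change ran from −2.31 to 8.06 without single samples and turned positive without NOD control 2, which left 49 control cells. Of 214 values of 19 gene results in the strain contrast 199 were kept and 15 lost the call. Where leaving out a sample left 1 in a group, that sample was assumed to vary like the others. In the knockout contrast, genes called in nmSC went from 82 to 53 with DESeq2, 175 without a filter (69 up and 106 down), 45 after thinning, 127 with the replicate block, 3 with the knockout libraries summed, 54 with nmSC and mySC merged, and 9 to 348 without single samples. In mySC they went from 195 to 317 with control libraries apart, 70 with DESeq2, 62 after thinning, 70 with the block, 121 with knockout libraries summed and 50 to 403 without single samples. In EC 14 became 32 with control libraries apart, 31 without a filter and 7 to 37 without single samples. In myeloid cells 576 became 294 with DESeq2, 359 after thinning, 202 with the block, 256 with knockout libraries summed and 349 to 501 without single samples. In lymphoid cells 1743 became 229 with DESeq2, 77 after thinning, 274 with the block (112 up and 162 down), 167 with knockout libraries summed (47 up and 120 down), 744 in CD4 cells alone and 262 to 2524 without single samples. The block, a fit paired by replicate number, rests on 2 shared numbers that the labels do not call pairs; gene-wise correlations across genes, which are not independent replicates, between differences within numbers ran from −0.0188 to 0.093. In the strain contrast, nmSC went from 175 to 83 with DESeq2, 286 without a filter, 33 after thinning, 79 with nmSC and mySC merged and 48 to 174 without single samples. In fibro cells 87 became 247 without a filter, 35 after thinning and 55 to 118 without single samples; in EC 41 became 79, 12 and 9 to 55. In myeloid cells 22 became 42 with control libraries apart, 11 with RLE size factors, 81 without a filter, 9 after thinning and 2 to 59 without single samples. In lymphoid cells 42 became 69 with control libraries apart, 72 without a filter, 17 after thinning, 20 with the batch term and 6 to 42 without single samples. The direction with more called genes turned under at least 1 alternative in 9 of the 10 sets. Types called by share in the knockout contrast went from 7 to 2 with the block, 0 with knockout libraries summed and 4 to 10 without single samples. Lists called by camera went from 30 of 49 to 1 with estimated correlation in the knockout contrast, and from 13 of 45 to 0 in the strain contrast, where leaving out samples gave 11 to 22. Restricted to cells with at least 1000 UMIs, C57BL/6 shares became 2.549% for MC, 9.849% for MP and 42.05% for fibro, and without doublets rat mast cells took 0.3062%. Thinned fits show what depth limits: with 20 mySC or 49 lymphoid cells per sample most calls of the full data were lost.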
